A study of Mus musculus with 12 samples.

How the data were processed

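Gene expression was measured on 12 arrays from mice lacking both Prkch and Apoe and from mice lacking Apoe alone, per the labels all backcrossed to C57BL/6J. Thioglycolate-elicited peritoneal macrophages were on 6 arrays, liver on 4 and aorta on 2. Total RNA was labelled with biotin, and the labels call the arrays of macrophages and liver biological replicates. Each aorta array held RNA pooled from 4 mice.

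The authors' arrays were processed with Affymetrix Expression Console, per the submitters' processing notes; its version, the algorithm and the reference set of arrays are not given in the sources used here. The deposited macrophage and liver values were taken as log2 probe set summaries, already background-corrected and normalized by the authors, because they are small positive numbers in the range of such summaries. The deposited aorta values were taken as linear intensity, scaled by the authors, because the mean signal without the lowest and highest 2% of probe sets was 100.04 on both arrays. No step of the authors' normalization was repeated.

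Exact ties between the deposited log2 values showed that the macrophage arrays were not all processed together. Control replicate 3 and knockout replicates 2 and 3 shared between 16075 and 18000 identical values per pair among 35557 probe sets, control replicates 1 and 2 and knockout replicate 1 shared between 53 and 69, and pairs across these sets shared between 0 and 3. These sets are called batch 1 (control replicates 1 and 2, knockout replicate 1) and batch 2 below. Of the macrophage genes tested, 66.1% had at least 2 identical values in batch 2. Liver pairs shared between 48 and 103 identical values, and their medians lay well below those of the macrophage arrays.

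Probe sets were named from the platform annotation. Of 35557 probe sets on the array used for macrophages and liver, 21789 had 1 gene symbol, 1621 had several and 12147 were not listed; of 22690 on the aorta array, 20393 had 1, 691 had several and 1606 were not listed. Symbols checked against the current gene table needed 0 updates. Only probe sets with 1 symbol were used, and a gene with several probe sets was represented by the one with the highest mean. Genes whose mean lay below the 30th percentile of all probe sets were left out, which kept 15039 genes in macrophages and 15942 in liver. In the aorta, genes were kept where the brighter array was at or above the median of all probe sets, a signal of 32.6, which kept 7098 of 12394 genes.

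Macrophages and liver were each fitted alone with limma (lmFit and eBayes, limma 3.58.1 in R 4.3.3), knockout minus control, with no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Another fit over all 10 of these arrays tested macrophage difference minus liver difference for 16363 genes. By the labels that contrast compares 2 settings, since sex, diet and age differ along with the tissue. The aorta has 1 array per genotype, so its differences have no replicate check and no p; they are given on the log2(signal + 16) scale, which understates changes of dim genes, and a gene was counted when its difference was at least 2-fold. All p-values measure the spread between these arrays as independent animals only as far as the labels name them so.

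Gene lists for lipid metabolism, inflammation, tissue remodelling, cell types and the chromosome region of Prkch were written before the data were examined, 46 lists with 692 entries in all. Lists with at least 5 measured members were tested with camera from limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry were run beside it. Aorta lists were set against 10000 random lists of the same size matched on mean signal. The tests, the filters, the lists and most alternatives were also chosen before the data were examined. The batch as a block, the interaction test of the lists, the alternatives for single lists and for the correlation between tissues, and added marker lists for the aorta were chosen after seeing the data.

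Genes were named by a fixed rule. Prkch was always named, followed by up to 12 called genes with the largest differences in each direction and no overlap between genotypes. Where fewer than 6 were called, the names were filled to 10 with the largest differences among genes with an unadjusted p under 0.05 and no overlap, which are described as not past the threshold. The aorta rule took the 12 largest differences in each direction, the interaction rule the 5 smallest p, and each described list up to 4 members with the smallest p, or in the aorta the largest difference. Predicted genes, pseudogenes, microRNAs, small nucleolar RNAs, olfactory receptors and vomeronasal genes were counted but not named. Genes named outside this rule were chosen after their values were seen.

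The computations were tested on simulated data without batches. For single genes, 200 were changed at once in each of 5 simulations. Recovery after Benjamini-Hochberg adjustment depends on that number, so the shares below do not hold where few genes change. In simulations of the macrophage design over 15039 genes, limma recovered 24.2%, 67.5% and 94.8% of genes changed by log2 0.5, 1 and 2, with a mean of 6.8 false calls. For the liver design over 15942 genes it recovered 0.30%, 23.6% and 77.0%, with a mean of 0.60 false calls. For the interaction over 16363 genes it recovered 2.69%, 40.3% and 88.2%, with a mean of 5.2 false calls. A list shifted by 0.5 was called by camera in 5 of 5 simulations of either design, and with an estimated correlation or fry in 5 of 5 for macrophages and 0 of 5 for liver. The simulated genes varied independently of each other. In the liver data the estimated correlation was 0.73 for cholesterol synthesis and 0.84 for macrophage markers. The simulations therefore do not check calls at the preset correlation for such lists. The number of arrays limits the precision of the array values.

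The alternatives tried were quantile normalization, median centring, no filter or a stricter filter on dim genes, the mean of a gene's probe sets, all 10 arrays in 1 fit, a trended prior, array weights, the replicate number as a block, age as a covariate in macrophages, a threshold of 0.1, other pseudocounts of 1 and 64 in the aorta, and leaving out each array in turn. Array weights stopped before convergence in the macrophage and interaction fits. Where leaving out an array left 1 array of a genotype, that array was assumed to vary like the others.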

Results

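Mice lacking Apoe, which clear lipoproteins poorly from the blood, were compared with mice that also lack Prkch, the gene of protein kinase C eta. Thioglycolate-elicited peritoneal macrophages came from females on regular diet, with 3 arrays per genotype and ages of 18, 17 and 27 weeks for replicates 1, 2 and 3 of each. Livers came from males aged 20 weeks after 12 weeks of high-fat diet, re-fed before sampling, with 2 arrays per genotype. Aortas came from fed males of that age and diet, with 1 array per genotype of RNA pooled from 4 mice. The control mice lack Apoe alone throughout. Array medians lay between 6.57 and 6.77 log2 units in macrophages and between 5.88 and 5.93 in liver; in the aorta they were 27.8 units of signal for the control pool and 30.1 for the knockout pool. Xist, transcribed from the inactive X chromosome of females, lay between 11.28 and 11.58 on the 6 macrophage arrays and between 4.11 and 4.37 on the 4 liver arrays, matching the labelled sexes.

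The targeted gene was lower in the knockouts of each tissue. In macrophages the brighter Prkch probe set read 9.94, 9.86 and 9.31 in control replicates 1 to 3 and 9.36, 8.79 and 8.87 in the knockouts, a difference of -0.70 ± 0.22 (SE, n = 3 and 3), or 61.6% of control by limma (Benjamini-Hochberg adjusted p = 1.00). Knockout replicate 1 lay above control replicate 3, which was processed in the other batch; within batches 1 and 2 the differences were -0.54 and -0.49, and -0.51 ± 0.05 with the batch as a block (limma, Benjamini-Hochberg adjusted p = 0.932). It was -0.58 without control replicate 1 and -0.62 without control replicate 2, and over all alternatives the adjusted p of limma ran from 0.0971 to 1.00. The dimmer macrophage probe set read 7.06, 7.14 and 6.85 in controls and 6.85, 6.62 and 6.62 in knockouts, a difference of -0.32. In liver the brighter probe set read 6.57 and 6.87 in controls against 5.93 and 5.65 in knockouts, a difference of -0.92 ± 0.16 (SE, n = 2 and 2), or 52.7% of control by limma (Benjamini-Hochberg adjusted p = 0.573). The dimmer liver probe set read 4.08 and 4.04 in controls and 3.94 and 4.21 in knockouts, a difference of 0.01. In the aorta the signal was 17.2 in the control pool and 9.94 in the knockout pool, both below the filter on dim genes. The labels do not say which part of the gene was removed, and a probe set outside that part does not check the genotype.

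**Figure D1:**
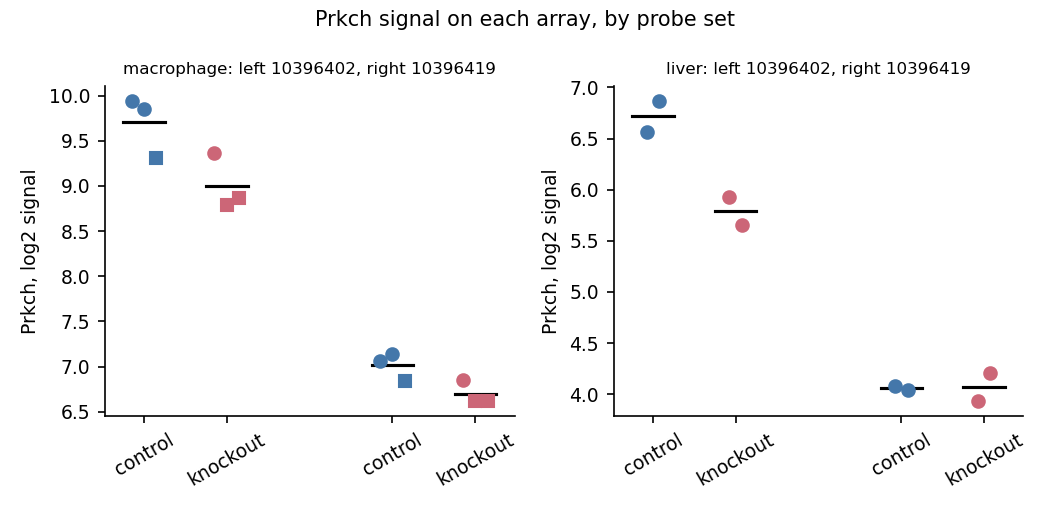
Prkch on each macrophage array (left) and liver array (right), in log2 units, for both probe sets; blue points are controls, red points knockouts, squares mark macrophage arrays of batch 2 and black lines group means. On the brighter probe set the means differed by -0.70 in macrophages and by -0.92 in liver.

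The macrophage comparison asks how loss of Prkch changes the resting transcriptome of elicited peritoneal macrophages in Apoe-deficient females. The largest difference was in Arg2, the mitochondrial arginase, which was 4.84-fold higher in knockouts, at 8.06, 10.42 and 9.15 log2 units against 6.70, 7.10 and 7.01 in controls. The chemokine receptor gene Ccr2, the transporter genes Slc38a6 and Slc44a1, and F10, which encodes coagulation factor X, were also higher on every knockout array than on any control. Irf7, a transcription factor of the interferon response, Gadd45a, a growth arrest gene, and Gas6, a ligand of phagocytic receptor kinases, were lower on every knockout array. None of these differences passed the threshold over all genes.

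The Arg2 difference was 2.28 ± 0.54 (SE, n = 3 and 3); it was 1.17 in batch 1, 2.78 in batch 2 and 1.97 with the batch as a block. Ccr2 differed by 0.54 (0.33 and 0.72 within batches 1 and 2, 0.53 with the block), Slc38a6 by 0.47 (0.37 and 0.58, block 0.47), Slc44a1 by 0.47 (0.62 and 0.19, block 0.40) and F10 by 0.29 (0.28 and 0.31, block 0.29). Tmem167 differed by 0.46, Phf11c by 0.39, Garre1 by 0.27, Senp6 by 0.24 and Rab2a by 0.22. Naming these genes required no overlap between the genotypes. The same direction within both batches was therefore fixed in advance, for higher and lower genes alike, and only the sizes were open. Among lower genes, Gadd45a differed by -0.66 (-0.39 and -1.03, block -0.71), Irf7 by -0.60 (-0.53 and -0.44, block -0.49) and Gas6 by -0.51 (-0.62 and -0.29, block -0.46). Vaultrc5 differed by -0.77, Cnrip1 by -0.71, Tm4sf1 by -0.55, Atp5k by -0.52, Grcc10 by -0.50, Riiad1 by -0.49 and Pdgfc by -0.49. With array weights, whose fit stopped before convergence, Ccr2 differed by 0.27, Garre1 by 0.096, Vaultrc5 by -0.47, Gadd45a by -0.30, Atp5k by -0.33 and Riiad1 by -0.28, and with the mean of its probe sets Slc44a1 by 0.28. Slc44a1 differed by 0.055 without control replicate 3 and by 0.20 without knockout replicate 2. Without knockout replicate 2 Ccr2 differed by 0.30, Phf11c by 0.25, Senp6 by 0.16, Vaultrc5 by -0.48, Cnrip1 by -0.44, Gadd45a by -0.43 and Irf7 by -0.37.

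Over 15039 genes limma with Benjamini-Hochberg adjustment called 0 higher and 0 lower, with a smallest adjusted p of 1.00. At an unadjusted p under 0.05 it gave 105 genes, 18 higher and 87 lower, where 752 are expected by chance in data without batches; with the batch as a block it again called 0 (smallest adjusted p = 0.932), with 205 genes at that unadjusted p. The genotypes did not overlap in 339 genes (2.25%), 98 higher and 241 lower in knockouts; no chance share is given, since the arrays fall into 2 batches and 41.2% of genes had a difference of exactly 0 within batch 2. The first principal component, 56.5% of the variance, set knockout replicate 2 at 36.8 and the other arrays between -18.8 and 3.4.

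Of 37 lists, 4 passed the macrophage test with the preset correlation, 3 lower and 1 higher. Mesothelium markers fell by 0.25 in median, with 7 of 8 members lower, among them Upk3b (-0.34), Krt19 (-0.72), Upk1b (-0.48) and Lrrn4 (-0.17). Camera of limma gave a Benjamini-Hochberg adjusted p = 0.0196, against adjusted p = 0.802 with an estimated correlation; the median was 0.04 in batch 1, -0.33 in batch 2 and -0.15 with the batch as a block (adjusted p = 0.0241). On knockout replicates 2 and 3 the mesothelium median was -0.40 and -0.46, that of fibroblast markers -0.64 and -0.45 and that of hepatic stellate cell markers -0.46 and -0.34. Neither of these other lists was called, with medians of -0.34 (5 of 6 lower, camera of limma, Benjamini-Hochberg adjusted p = 0.323) and -0.19 (5 of 7 lower, adjusted p = 0.355). Interferon response genes fell by 0.19 in median, with 17 of 21 lower, among them Irf7, Xaf1 (-0.28), Bst2 (-0.23) and Oas1a (-0.32). Camera of limma gave a Benjamini-Hochberg adjusted p = 0.0196, against adjusted p = 0.802 with an estimated correlation; the median was -0.19 in batch 1, -0.17 in batch 2 and -0.14 with the block (adjusted p = 0.00578).

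Fatty acid oxidation genes fell by 0.11 in median in macrophages, with 16 of 18 lower, among them the thiolase gene Acaa2 (-0.31), the lipase inhibitor gene Angptl4 (-0.72) and Acadvl (-0.12), while Fgf21 differed by 0.12. The Benjamini-Hochberg adjusted p of limma's camera was 0.0417, against adjusted p = 0.802 with an estimated correlation; the median was 0.0038 in batch 1, -0.19 in batch 2 and -0.09 with the block (adjusted p = 0.00578). Oxidative stress response genes rose by 0.05 in median, with 11 of 17 higher, among them the cystine transporter gene Slc7a11 (0.48), Txnrd1 (0.11), Nqo1 (0.18) and Cybb (0.15). Their adjusted p by limma's camera with Benjamini-Hochberg was 0.0417, against adjusted p = 0.802 with an estimated correlation; the median was -0.08 in batch 1, 0.10 in batch 2 and 0.04 with the block (adjusted p = 0.991). In these 4 lists 0 members were called over all genes and 0 when adjusted over the list alone. Over the 37 lists both camera with an estimated correlation (0 at an unadjusted p under 0.05) and fry (smallest adjusted p = 0.714) called 0. The B cell markers, which were not called over all arrays (adjusted p = 0.0866), had a median of 1.54 above controls on knockout replicate 2, where Ms4a1, named after its values were seen, read 10.13 against 6.46 to 8.26 on the other 5 arrays. MHC class II genes likewise had a median of 0.65 above controls on that array (adjusted p = 0.0689 over all arrays).

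Each macrophage list call depended on single arrays. Without control replicate 3, 0 lists passed camera of limma, with Benjamini-Hochberg adjusted p = 0.398 for mesothelium markers, 0.286 for interferon response, 0.868 for fatty acid oxidation and 0.0573 for oxidative stress. Without knockout replicate 2 the medians of these lists were -0.16, -0.07, -0.03 and -0.05, so oxidative stress changed direction, with adjusted p = 0.0134, 0.0697, 0.356 and 0.617. The interferon call was also lost without knockout replicate 1 (adjusted p = 0.453), the fatty acid oxidation call without knockout replicate 1 (0.0632), the mesothelium call without knockout replicate 3 (0.0585), and the oxidative stress call without control replicate 1 (0.354) or knockout replicate 3 (0.175). Over all alternatives the adjusted p ran from 7.9e-04 to 0.981 for mesothelium, 2.2e-06 to 0.981 for interferon, 5.8e-04 to 0.981 for fatty acid oxidation and 2.2e-05 to 0.991 for oxidative stress. The number of lists called was 11 without control replicate 1, 10 without knockout replicate 1, 6 without control replicate 2 or without knockout replicate 3, and 5 without knockout replicate 2. In that last fit the smallest adjusted p belonged to mast cell markers, with a median of -0.48 (adjusted p = 2.3e-13, against 0.438 over all arrays, with 0.43 on the array left out), and macrophage markers had a median of -0.11 (adjusted p = 0.00335, against 0.349 over all arrays). Without knockout replicate 2 the B cell markers had a median of -0.37 (adjusted p = 1.8e-04, in a range of 1.8e-04 to 0.996 over the alternatives run for that list), and the MHC class II median became -0.13 (adjusted p = 0.0148, in a range of 0.0148 to 0.996).

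The liver comparison asks how loss of Prkch changes the liver of re-fed, high-fat-fed Apoe-deficient males. Genes of cholesterol synthesis were higher together: Idi1, which makes the building block of isoprenoids, rose 3.45-fold, and all 20 measured members of the pathway were higher in knockout livers. Genes of macrophages, scavenger receptors, MHC class II antigen presentation and fatty acid oxidation were lower at the preset correlation between genes. With an estimated correlation camera of limma called none of these groups, cholesterol synthesis included (Benjamini-Hochberg adjusted p = 0.731 for each). The largest single difference was in Gpnmb, a glycoprotein gene of lipid-laden macrophages, at 5.45 and 8.34 log2 units in knockouts against 9.27 and 9.34 in controls.

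Idi1 read 8.19 and 7.94 in controls and 9.99 and 9.71 in knockouts, a difference of 1.79 ± 0.16 (SE, n = 2 and 2; limma with Benjamini-Hochberg, adjusted p = 0.0463). It was the 1 gene called higher among 15942, and 0 were called lower. At an unadjusted p under 0.05 limma gave 684 genes, 246 higher and 438 lower, where 797 are expected by chance. The genotypes did not overlap in 4744 genes (29.8%), where chance gives 33.3%. The Idi1 call was lost with quantile normalization (limma adjusted p = 0.0681) and without the filter on dim genes (limma adjusted p = 0.0722). It was also lost with all 10 arrays in 1 fit (limma adjusted p = 0.253) and with a trended prior (limma adjusted p = 0.0554). Leaving out control replicate 1 or knockout replicate 1 ended it as well. Over all alternatives the adjusted p of limma ran from 2.6e-04 to 0.253, though the difference stayed between 1.65 and 1.95. Without knockout replicate 2 the counts were 17 higher and 22 lower, and without control replicate 2 they were 1 higher, Idi1, and 2 lower, Themis and Cyp2a22, which was named after its value was seen. In each fit without 1 array, the genotype left with 1 array is assumed to vary like the other.

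Cholesterol synthesis genes rose by 0.76 in median in liver, with 20 of 20 members higher, 16 called when adjusted over the list alone and 1 over all genes. Camera of limma gave a Benjamini-Hochberg adjusted p = 3.6e-34, against adjusted p = 0.731 with an estimated correlation and 0.644 with fry. Beside Idi1, the sterol oxidase gene Msmo1 differed by 1.45 ± 0.20, Dhcr7, the last enzyme of one branch of the pathway, by 1.01 ± 0.15, and Cyp51, the lanosterol demethylase gene, by 1.28 ± 0.24 (SE, n = 2 and 2). Sqle, squalene epoxidase, had the largest difference of the pathway at 1.97 ± 0.39, or 3.93-fold. The median member was 0.97 above controls in knockout replicate 1 and 0.52 above in knockout replicate 2. Hepatocyte markers differed by a median of 0.06.

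**Figure D2:**
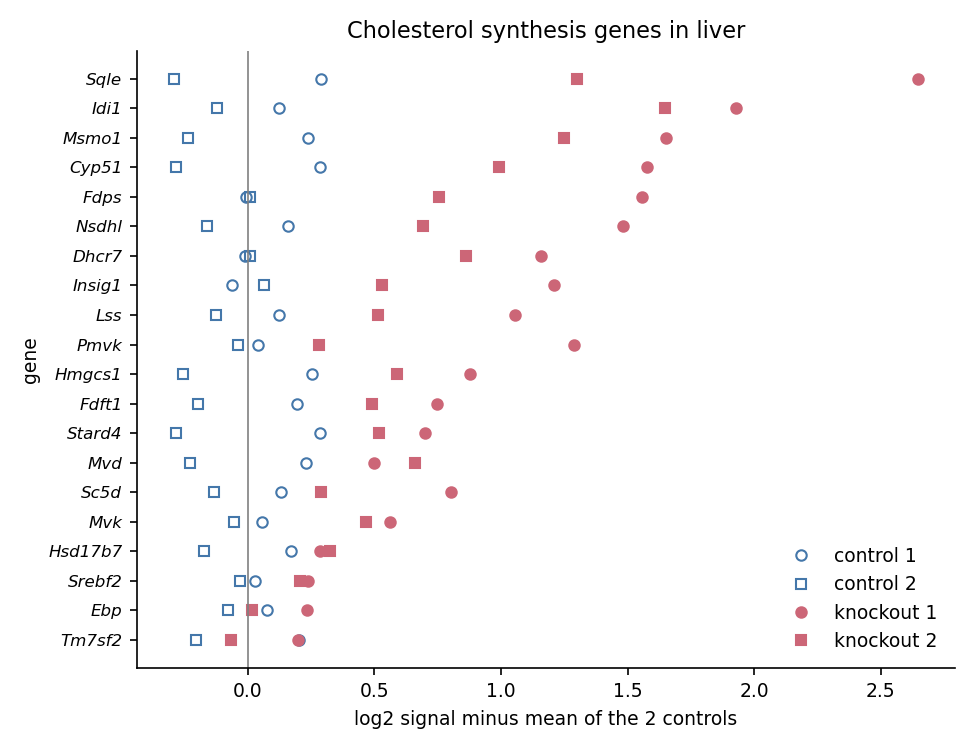
The 20 measured cholesterol synthesis genes on the 4 liver arrays, as log2 value minus the mean of the controls; open blue points are controls and filled red points knockouts, circles replicate 1 and squares replicate 2. Of the 20 genes, 19 lay above both controls in knockout replicate 1 and 18 in knockout replicate 2.

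Fatty acid and triglyceride synthesis genes rose by 0.11 in median, with 14 of 22 higher and 0 called when adjusted over the list alone. The Benjamini-Hochberg adjusted p of limma's camera was 0.0261, against adjusted p = 0.731 with an estimated correlation. Fasn, fatty acid synthase, differed by 1.02 ± 0.33, Acacb by 0.69 and Acaca by 0.44, while the desaturase gene Scd2 differed by -0.61. Fatty acid oxidation genes fell by 0.32 in median, with 22 of 23 lower and 0 called when adjusted over the list alone. Camera of limma gave a Benjamini-Hochberg adjusted p = 2.8e-07, against adjusted p = 0.731 with an estimated correlation. Among them Pex11a, a peroxisome gene, differed by -1.02, Acaa1b by -0.61, Angptl4 by -0.61 and the hormone gene Fgf21 by -0.41.

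Genes of macrophages and lipid uptake were lower in knockout livers. Scavenger receptor and lipid uptake genes fell by 0.36 in median, with 16 of 16 lower and 7 called when adjusted over the list alone, among them Pparg (-1.06), Cd5l (-0.62), the fatty acid receptor gene Cd36 (-1.11) and Colec12 (-0.46). Macrophage markers fell by 0.32, with 11 of 11 lower and 1 called when adjusted over the list alone, among them Cd68 (-0.84), Lyz2 (-0.65), C1qc (-0.47) and C1qa (-0.46). MHC class II antigen presentation genes fell by 0.32, with 14 of 14 lower and 0 called when adjusted over the list alone, among them H2-Ab1 (-0.94), Cd74 (-0.81), H2-Aa (-0.77) and H2-Eb1 (-0.86). Kupffer cell markers fell by 0.30, with 8 of 8 lower and 1 called when adjusted over the list alone, among them Cd5l, Vsig4 (-0.76), Timd4 (-0.64) and Cdh5 (-0.19). In that order, camera of limma gave Benjamini-Hochberg adjusted p = 1.9e-07, 2.9e-06, 3.1e-06 and 0.00436, against adjusted p = 0.731 with an estimated correlation for each. The Kupffer cell median was 0.14 above controls in knockout replicate 1 and was -0.62 in knockout replicate 2, with control medians of -0.22 and 0.22. For macrophage markers the medians were -0.20 and 0.20 on control replicates 1 and 2, and -0.47 and -0.30 on the knockouts. Macrophage markers vary together, with an estimated correlation of 0.84, so the 11 lower members are not independent observations.

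Lysosomal enzyme and macrophage protease genes fell by 0.16 in median in liver, with 13 of 16 lower and 5 called when adjusted over the list alone, among them the elastase gene Mmp12 (-1.81), Gpnmb (-2.41), Ctsb (-0.43) and Ctsd (-0.55). Cholesterol efflux and LXR target genes fell by 0.21, with 14 of 16 lower and 1 called when adjusted over the list alone, among them Pltp (-0.75), Nceh1 (-0.53), Abcg8 (-0.60) and Abcg1 (-0.48). Oxidative stress response genes fell by 0.28, with 15 of 16 lower and 1 called when adjusted over the list alone, among them Hmox1 (-0.64), the metallothionein genes Mt2 (-0.90) and Mt1 (-0.63), and Srxn1 (-0.39). Extracellular matrix genes fell by 0.19, with 22 of 24 lower and 0 called when adjusted over the list alone, among them Col3a1 (-0.63), Sparc (-0.91), Col1a2 (-0.45) and Mmp2 (-0.34). Inflammatory genes driven by NF-kB fell by 0.18, with 19 of 23 lower and 0 called when adjusted over the list alone, among them Ccl2 (-0.64), Vcam1 (-0.66), Icam1 (-0.50) and Tnfaip3 (-0.59). In that order, camera of limma gave Benjamini-Hochberg adjusted p = 1.7e-04, 2.8e-05, 1.1e-05, 1.1e-05 and 1.7e-04, against adjusted p = 0.731 with an estimated correlation for each.

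**Figure D3:**
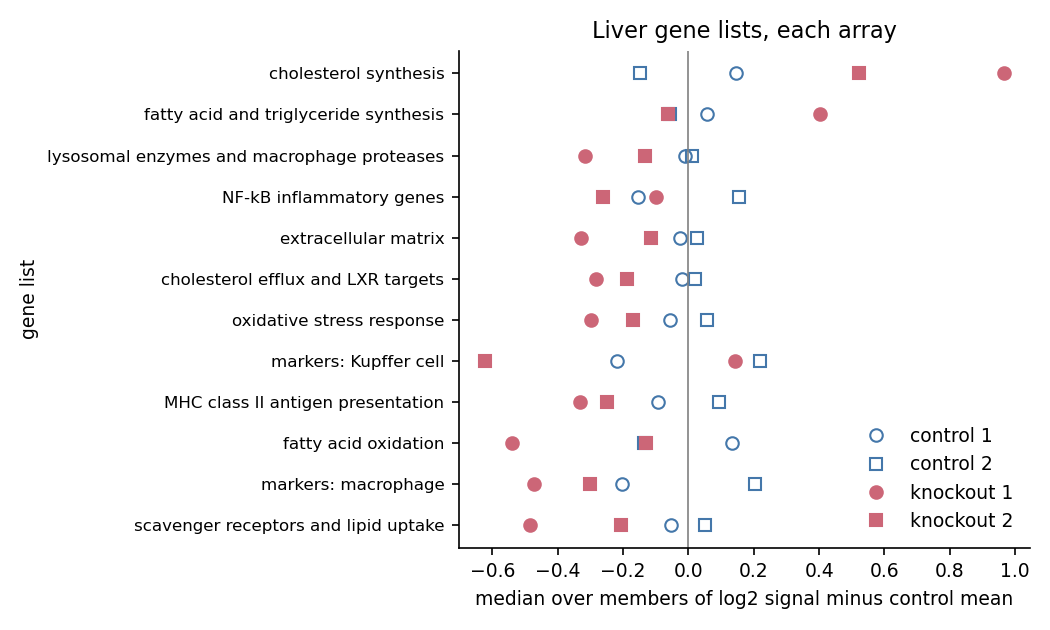
The 12 gene lists called in liver, each shown by the median log2 difference of its members from the mean of the controls on each of the 4 arrays; open blue points are controls and filled red points knockouts. Cholesterol synthesis lay at 0.97 and 0.52 on the knockout arrays, and the Kupffer cell markers lay on both sides of 0.

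Of 39 lists tested in liver, camera with the preset correlation called 12, 2 higher and 10 lower, and both camera with an estimated correlation (smallest adjusted p = 0.731, 1 list at an unadjusted p under 0.05) and fry called 0. Single arrays decided several of the calls, by limma's camera with Benjamini-Hochberg adjustment. Without knockout replicate 1, fatty acid oxidation (adjusted p = 0.178, in a range of 1.8e-12 to 0.731 over its alternatives), extracellular matrix (0.270, range 2.1e-08 to 0.731) and fatty acid synthesis (0.843, range 3.5e-06 to 0.843, median -0.06) were no longer called. Without knockout replicate 2, the NF-kB list (0.10, range 1.8e-11 to 0.731) and the Kupffer cell markers (0.754, range 1.9e-09 to 0.806, median 0.14) were not called. Without control replicate 2, the same pair (0.455 and 0.576), fatty acid synthesis (0.246) and macrophage markers (0.226, range 7.2e-15 to 0.731) were not called.

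Other large liver differences did not pass the threshold over all genes. Fdps, farnesyl diphosphate synthase, differed by 1.16 and Nsdhl, another sterol enzyme, by 1.09. Gask1a differed by 1.08, Cyp39a1, an oxysterol hydroxylase, by 1.06 and the trefoil factor gene Tff3 by 1.02. Themis, a gene of T cell selection, differed by -1.55, Ly6d by -1.46, Fitm1, a lipid droplet gene, by -1.30, Cyp2c38 by -1.20, the galectin gene Lgals1 by -1.17, Zfp991 by -1.16, Mogat1, an enzyme of triglyceride synthesis, by -1.14 and Gpr137b by -1.12. Mmp12 read 6.44 and 7.87 in knockouts against 9.02 and 8.91 in controls. Gask1a and Cyp39a1 were higher in knockout replicate 2 (7.26 and 8.15) than in knockout replicate 1 (7.06 and 7.85), and without knockout replicate 1 the differences of Themis, Zfp991 and Lgals1 moved by less than 1.5 times. Other genes moved by more than that without this array: Gpnmb differed by -0.97, Sqle by 1.30, Mmp12 by -1.09, Ly6d by -0.55, Fasn by 0.42, Fdps by 0.75, Nsdhl by 0.69, Tff3 by 0.53, Cyp2c38 by -0.64, Mogat1 by -0.73 and Gpr137b by -0.74, and none passed the threshold. Without knockout replicate 2 these genes passed: Gpnmb (-3.86), Sqle (2.65), Mmp12 (-2.52), Ly6d (-2.38), Cyp2c38 (-1.75), Fitm1 (-1.69), Msmo1 (1.65), Themis (-1.65), Fasn (1.63), Fdps (1.56), Tff3 (1.51), Gpr137b (-1.50) and Nsdhl (1.48). Without control replicate 2 Themis passed (-1.74), and without control replicate 1 Lgals1 and Mogat1 differed by -0.74 each.

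The difference between the macrophage and the liver effect was tested directly. Cholesterol synthesis genes were higher in knockout liver, with a median of 0.76, than in knockout macrophages, with a median of -0.0046. In macrophages the mean of the list, 0.04, and the direction of its test were opposite in sign to the median, and with the batch as a block the list passed upward with a median of 0.14 (camera of limma, Benjamini-Hochberg adjusted p = 0.00578, against adjusted p = 0.879 with an estimated correlation, in a range of 0.00578 to 0.997 over its alternatives). Scavenger receptor, MHC class II and macrophage marker genes were lower in knockout liver, with liver medians of -0.36, -0.32 and -0.32 against 0.02, 0.14 and -0.0048 in macrophages. Without macrophage knockout replicate 2 these macrophage medians were -0.0077, -0.13 and -0.11. Of 41 lists, camera of limma called 10 for this contrast at the preset correlation, and 0 with an estimated correlation (smallest Benjamini-Hochberg adjusted p = 0.368).

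Of 16363 genes, limma called 0 for the contrast (smallest Benjamini-Hochberg adjusted p = 0.528), with 345 at an unadjusted p under 0.05. The smallest p belonged to Themis, with macrophage minus liver 1.59 ± 0.22 (SE), followed by Rdh16f2 at -1.28, Zfp991 at 1.06, Msmo1 at -1.46 and Mfsd2a, a lipid transporter gene, at 0.90. Without liver knockout replicate 2 limma called 1 gene, Gpnmb at 3.69, which was named after its value was seen.

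The aorta comparison asks what differs in the aorta samples of the same high-fat-fed males, on 1 pool per genotype, so nothing below was tested. Adrenal, lymph node or muscle tissue beside the aorta in a pool cannot be told apart from a genotype effect in the vessel. Among the largest differences were 3 genes that act in steroid hormone synthesis, a group not tested as a list: Hsd3b1 read 563 in the knockout pool against 0.806 in the control pool, Star 302 against 15.3 and Cyp11a1 117 against 1.45. Genes of B and T cells were higher, with Ms4a1 at 453 against 49.9 and Cd3d at 87.5 against 6.08. Genes of skeletal muscle were lower, with Ryr1 at 48.1 against 222 and Myh2 at 465 against 1324.

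Of 7098 kept genes, 62 were at least 2-fold higher and 28 at least 2-fold lower in the knockout pool on the log2(signal + 16) scale, while 91.7% lay within 0.5 log2 units and the SD of all differences was 0.33. These counts depend on the pseudocount: they were 111 and 58 with a pseudocount of 1, and 25 and 12 with one of 64. On the log2(signal + 16) scale, by the brightest probe set of each gene, the largest differences were Hsd3b1 (5.11), the reductase gene Akr1cl (3.59), Star (3.34), the antibody gene Igkv8-30 (3.17), Mgarp (2.95), Cyp11a1 (2.93), Ms4a1 (2.83), Hao2 (2.82), Jchain (2.80), the transporter gene Abcb1b (2.56), Cd3d (2.23) and the secretory granule gene Chga (2.13). The largest in the other direction were Trdn (-2.08), the calcium channel gene Ryr1 (-1.89), Fbxo32 (-1.86), the myosin gene Myh7 (-1.85), Actn3 (-1.56), the calcium pump gene Atp2a1 (-1.55), Myh2 (-1.48), Smtnl1 (-1.44), Apobec2 (-1.44), Tnnt1 (-1.39), Ptp4a3 (-1.31) and titin, Ttn (-1.29). Of the 5 other probe sets of Trdn only 2 went the same way, and with the mean of its probe sets Trdn differed by -1.19. A second probe set of Ptp4a3 went the other way. Hybridization controls read a median of 1.41 times higher in the knockout pool, between 1.26 and 2.05 times, while the scaled mean signals were 100.04 in both. Poly-A controls had a median ratio of knockout to control pool of 1.32, between 0.78 and 3.80, and the 18S probe sets had ratios between 0.49 and 0.78.

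**Figure D4:**
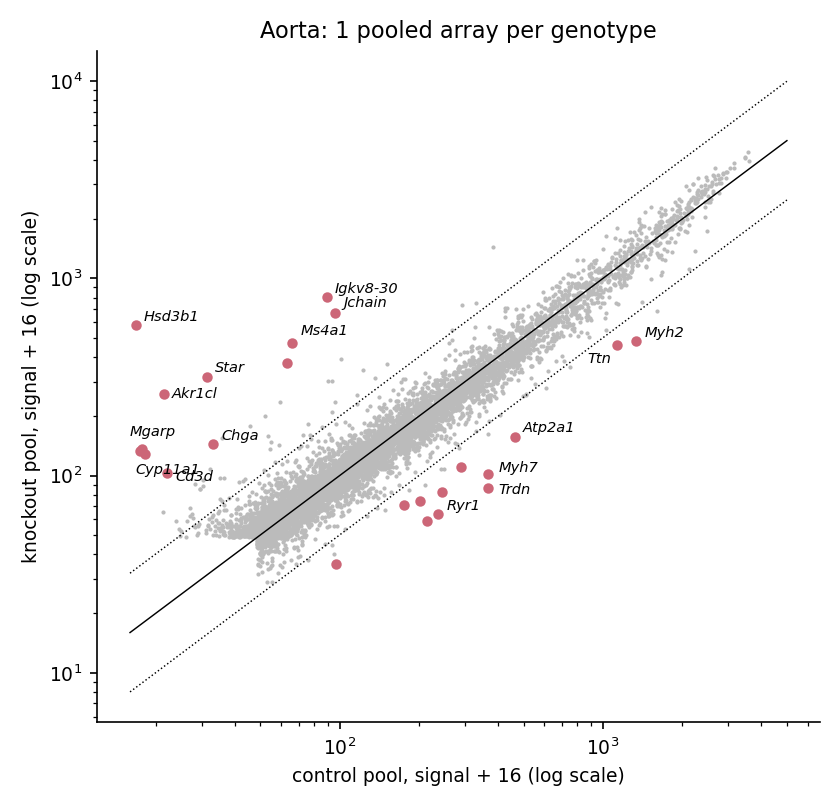
Signal plus 16 in the control pool (horizontal) and the knockout pool (vertical) for the 7098 kept aorta genes, both on log axes; red points are the named genes, the solid line marks equality and the dotted lines 2-fold. Hsd3b1, at 0.806 and 563 before the addition, lies farthest from equality.

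Of 31 aorta lists, 7 lay above and 4 below the central 95% of matched random lists. B cell markers had a median difference of 1.31, with 6 of 7 kept members higher, among them Cd79b at 162 against 29.8 and Ighm at 1431 against 366. T cell markers had a median of 0.95, with 5 of 5 higher, and MHC class II genes one of 0.68, with 9 of 9 higher, among them H2-Oa at 52.7 against 11.1. Cell cycle genes had a median of 0.57, with 10 of 10 higher, among them Mcm2 at 69.0 against 13.4, Rrm2 at 58.3 against 19.9 and Mki67 at 45.6 against 16.8. Acute phase genes had a median of 0.48, with 7 of 8 higher, among them Saa3 at 195 against 77.4. Smooth muscle markers had a median of 0.24 and extracellular matrix genes one of 0.17, among them Lum at 692 against 417. Skeletal muscle markers had a median of -0.79, with 10 of 10 lower. Endothelium markers had a median of -0.28, immediate early genes one of -0.25 and fatty acid oxidation genes one of -0.22, with Ppargc1a at 91.8 against 228 and Cpt1a, which went the other way, at 161 against 69.4. The filter keeps a gene when either pool is bright, which favours members that differ. Without it the medians were 0.82 for B cell markers (9 of 10 higher), 0.56 for T cell markers (10 of 10), 0.63 for MHC class II genes (13 of 13) and 0.30 for cell cycle genes (24 of 26), each above the central 95%. Acute phase genes (0.093, 12 of 18 higher), fatty acid oxidation genes (-0.13) and endothelium markers (-0.23) then lay inside it.

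The genotype differences of the tissues were compared across genes, which are not independent replicates. Between macrophages and liver the differences of 14617 genes had a Pearson r of 0.073 and a Spearman rho of 0.061. Of the genes at an unadjusted p under 0.05, 3 were higher in both, where independent lists give 0.24, and 4 lower in both, where they give 2.20. The targeted gene Prkch itself met this rule as lower in both (limma, unadjusted p = 0.0161 and 4.5e-04). Slc38a6, near it on chromosome 12, met it as higher in both (limma, unadjusted p = 0.00323 and 0.0218). The Pearson r was 0.070 between macrophages and aorta and 0.018 between liver and aorta. Without macrophage control replicate 3, macrophage knockout replicate 2 or liver knockout replicate 2 the macrophage and liver r was 0.044, 0.022 or 0.038.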

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

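Of the tests below, the interaction test of the lists and the tests on the liver and on Slc38a6 were chosen after the result was seen, as were the marker lists for the aorta, though not what each of these lists had to show.

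Results stood out where the genotype difference in macrophages minus that in liver passed the interaction test of camera in limma, with Benjamini-Hochberg adjustment, at the preset correlation. Cholesterol synthesis genes had a median contrast of -0.68 (adjusted p = 2.2e-19, and 0.368 with an estimated correlation). Oxidative stress response genes had one of 0.43 (adjusted p = 2.9e-06, and 0.368 with an estimated correlation). MHC class II genes had one of 0.46 (adjusted p = 2.9e-06, and 0.575 with an estimated correlation), and macrophage markers one of 0.45 (adjusted p = 7.7e-05, and 0.575). The macrophage side of both depended on knockout replicate 2. Without that array the macrophage median moved from 0.14 to -0.13 for MHC class II genes and from -0.0048 to -0.11 for macrophage markers. For fatty acid oxidation it was 0.27 (adjusted p = 2.1e-04, and 0.575 with an estimated correlation), and for scavenger receptors 0.46 (adjusted p = 2.8e-04, and 0.368). For mesothelium markers it was -0.35 (adjusted p = 0.00522, and 0.575 with an estimated correlation), and for inflammatory genes driven by NF-kB 0.19 (adjusted p = 0.0258, and 0.575). For Kupffer cell markers it was 0.42 (adjusted p = 0.0473, and 0.575 with an estimated correlation), and for efflux and LXR targets 0.085 (adjusted p = 0.0494, and 0.368).

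Ccr2, Garre1 and Vaultrc5 stood out because every macrophage knockout array lay on one side of its controls and every liver knockout array on the other. They were sought only among the named genes, and each was named in macrophages, where naming required no overlap. In liver the genotypes did not overlap in 29.8% of all genes, where chance gives 33.3%. Opposite sides in these genes therefore cannot be told apart from chance. The macrophage minus liver contrast was 1.25 for Ccr2, 0.37 for Garre1 and -1.63 for Vaultrc5, and none passed limma's interaction test (Benjamini-Hochberg adjusted p = 1.00 for each). The liver differences were -0.71 for Ccr2, -0.10 for Garre1 and 0.85 for Vaultrc5.

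In the aorta, Hsd3b1, Star and Cyp11a1, which act in steroid synthesis and were picked for their large differences, and the B and T cell markers were higher in the knockout pool. The count of genes at least 2-fold higher, 61 after quantile normalization and 62 before, tests scaling little, since that step moved the median of all genes by -0.012. Scaling is argued against for these genes by their values over all alternatives, quantile normalization and median centring among them. Hsd3b1, Star and Cyp11a1 stayed at least 3.27, 2.21 and 1.47 higher, and the B cell median at least 0.58. Adrenal tissue beside the aorta in that pool may contribute but cannot be told apart from a genotype effect: 5 kept adrenal cortex markers not among the named genes had a median of 0.63, with Cyp21a1 at 49.2 against 5.4 and Mc2r at 44.3 against 16.1, while the 3 brightest, which the control pool also expressed, read 798 against 629 (Fdx1), 409 against 437 (Mrap) and 242 against 151 (Scarb1, also in the efflux list). Lymph node tissue cannot be told apart either, since only 3 of its markers were kept, Cxcl13 at 287 against 77.5, Clu at 1421 against 1272 and Glycam1 at 33.9 against 27.3. The labels name perfusion with saline and no step that would remove either tissue or skeletal muscle, whose markers differed by a median of -0.79, and a genotype effect in the vessel was not tested, with 1 pool per genotype.

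In liver, cholesterol synthesis genes were higher in both knockout arrays. A larger share of hepatocytes is argued against, since hepatocyte markers had a median of 0.059 where the lower quartile of the pathway was 0.54. Knockout replicate 1 did not carry the difference alone. Without it the median was 0.52, and 18 of 20 members lay above both controls in knockout replicate 2. The control medians were 0.15 and -0.15. The members vary together, with an estimated correlation of 0.73, so these 18 are not independent observations. They rest on 1 array, and chance between arrays is not excluded. A difference in feeding state cannot be told apart from a genotype effect, since fatty acid synthesis genes, which feeding also raises, had a median of 0.11 and an upper quartile of 0.44, above the bound of 0.38 set for excluding it. An effect of Prkch on sterol synthesis may add to it and was not tested apart from feeding.

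Slc38a6, which lies near Prkch on chromosome 12, was higher in knockout macrophages (0.47 ± 0.10) and in knockout liver (0.48 ± 0.17), without passing the threshold over all genes in either. With the batch as a block the macrophage difference was again 0.47. The gene was named for no overlap between the genotypes in macrophages, so a higher signal within each batch was fixed in advance. Only the size was open, and it did not fall with the block. The processing batch was not put to a further test. A strain variant under the Slc38a6 probes, which lowers a signal, was not put to a test that could decide. The gene was picked for its higher signal, by 4.50 standard errors in macrophages and 2.83 in liver, so that outcome was fixed in advance. Chance cannot be told apart: the combined p of 0.0223, adjusted over 30 neighbours, was chosen after the values were seen and is built from those for which the gene was picked. As a hypothesis, the altered Prkch locus may act on Slc38a6, which was not tested.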

How the results depend on the processing

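The tests with the batch as a block, on single lists, on the interaction's named genes and on the correlation between tissues were chosen after the result was seen. The cause of the changes below was not tested.

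In macrophages, where 4 lists passed, 2 passed with median centring, 2 without the filter on dim genes and 2 with array weights, whose fit stopped before convergence; 9 passed at an adjusted p under 0.1, 0 with an estimated correlation and 0 by fry. Leaving out 1 array gave 0 to 11 lists and a Prkch difference of -0.89 to -0.58. With array weights the direction of camera reversed for fatty acid oxidation (median -0.12) and interferon response (-0.031), and the mesothelium call was lost. Quantile normalization, median centring and no filter each ended the calls of fatty acid oxidation and oxidative stress. The former was also lost with all 10 arrays in 1 fit, the latter with the 50th percentile filter. Leaving out 1 array took the oxidative stress median from -0.052 to 0.13. Age as a covariate changed no call, and limma called 0 genes in each macrophage alternative.

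In liver, 0 genes were called higher with quantile normalization, 0 without the filter, 0 with all 10 arrays in 1 fit and 0 with a trended prior, against 1; leaving out 1 array gave 0 to 17 higher and 0 to 22 lower. Of the 12 lists, 0 passed with an estimated correlation and 0 by fry, where the cholesterol synthesis median is 0.76 as before. Leaving out 1 array took the median of fatty acid synthesis from -0.063 to 0.40 and that of Kupffer cell markers from -0.62 to 0.14. The interaction gave 0 to 1 genes when 1 array was left out. The macrophage and liver correlation of 0.073 was 0.035 without the filter, 0.11 with the 50th percentile filter and 0.022 to 0.093 when 1 array was left out.

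The replicate numbers were tested as pairs. Same-numbered macrophage arrays had correlations of 0.40, 0.03 and 0.50 of their deviations, and the liver value was 0.11. Knockout replicate 2 correlated best with control replicate 3 (0.07), but its same-numbered control was processed in the other batch. Within batch 1, knockout replicate 1 correlated more with control replicate 1 (0.40) than with control replicate 2 (0.19). Within batch 2, control replicate 3 correlated more with knockout replicate 3 (0.50) than with knockout replicate 2 (0.07). The correlations therefore cannot decide whether the numbers mark pairs. Same-numbered macrophage arrays also share an age per the labels, which name no shared litter, batch or day, and the numbers were not taken as pairs. With the replicate block, limma called 0 macrophage genes (201 at an unadjusted p under 0.05) and 10 lists, and in liver 11 genes higher and 12 lower. Of the named liver genes, Idi1, Sqle, Msmo1, Cyp51, Fdps, Nsdhl, Gask1a and Cyp39a1 passed as higher in that fit. Mmp12, Themis, Fitm1, Zfp991 and Gpr137b passed as lower.

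In the aorta, where 62 genes were higher and 28 lower, median centring, which moved the median of all genes by -0.10, gave 55 and 45. The 70th percentile filter gave 39 higher. A pseudocount of 1 gave 111 higher, 58 lower and a Prkch difference of -0.73, and one of 64 gave 25 and 12. Without the filter, fatty acid oxidation (-0.13), acute phase (0.093) and endothelium (-0.23) moved inside the random range. Of the values of named aorta genes 30 moved by more than the spread, such as Hsd3b1 from 5.11 to 8.29 and 3.27 and Cyp11a1 from 2.93 to 5.59 and 1.47 with pseudocounts of 1 and 64.

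Of the remaining values, 337 for named macrophage genes, 226 for named liver genes, 94 for interaction genes and 136 for named aorta genes kept both direction and side of the threshold or moved less than the spread. No named macrophage or interaction gene passed in any setting, so for these only a change of direction could show. Slc44a1 at 0.055 and Garre1 at 0.096 count among the values kept. For liver genes 26 newly passed and 6 no longer did; list calls ended with their direction kept in 29 macrophage and 32 liver cases, and with it reversed in 3 and 2.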

Other observations

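The splits of the macrophage arrays and the tests of the neighbours of Prkch over both tissues were chosen after the result was seen, apart from the split test of the lists.

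Several groups of genes tied to the knockout or to the tissues' condition passed no test. The other protein kinase C genes were slightly higher in knockout macrophages, 11 of 11 members with a median of 0.02 (camera of limma, Benjamini-Hochberg adjusted p = 0.106), and in liver their median was 0.02 with 8 of 12 higher (adjusted p = 0.996). Cell cycle genes had a macrophage median of -0.11, with 21 of 26 lower (adjusted p = 0.0866), and in the aorta they lay above the matched random lists. Alternative activation genes had a macrophage median of 0.08 (adjusted p = 0.255).

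In liver, acute phase genes had a median of 0.11 (camera of limma, Benjamini-Hochberg adjusted p = 0.176), bile acid genes one of -0.09 (adjusted p = 0.432), and circadian clock genes one of -0.09 (adjusted p = 0.191). Endothelium markers were lower in 10 of 10 members with a median of -0.07 (adjusted p = 0.235). Interferon response genes had a liver median of -0.06 (adjusted p = 0.770), and in the aorta 13 of 14 were higher with a median of 0.15, inside the central range of random lists, though above it without the filter (0.17, 20 of 21 higher).

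The 6 macrophage arrays make only 10 splits into 3 and 3, too few for a share under 0.05. For genes called by limma the real split gave 0 (105 at an unadjusted p under 0.05), which any split must reach, so this count says nothing of chance; the highest other gave 5073. That split is the processing batch and points to a structure of the samples; with the batch as a block limma again called 0 genes (205 at an unadjusted p under 0.05). For lists, 8 splits gave at least the 4 of the real one, and the highest other gave 13.

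The neighbours of Prkch as a list had a median of -0.0046 in macrophages and a mean of 0.02 with the test upward (camera of limma, Benjamini-Hochberg adjusted p = 0.230). Beside Slc38a6, the smallest combined p belonged to Gpx2 (0.143 adjusted over 30 neighbours), which went opposite ways, -0.21 in macrophages and 0.49 in liver.

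In the aorta, adrenal medulla markers had a median of 0.08, with Chgb at 375 against 84.9 and Scg2 at 222 against 80.1 higher, and Dbh at 97.8 against 122 and Npy at 460.2 against 531 lower. The ratio of 3' to 5' signal was 0.92 against 0.81 for Gapdh and 1.90 against 1.39 for actin, knockout pool first.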
